A study of Mus musculus with 18 samples.

How the data were processed

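Reduced representation bisulfite sequencing was applied to macrophages and endothelial cells sorted by flow cytometry from the ischemic gastrocnemius muscle of mice, 1 week after ligation of the femoral artery. The method cuts genomic DNA with a restriction enzyme, keeps short CpG-rich fragments and reads methylated cytosines after bisulfite conversion. Per the labels, 18 samples form 6 groups of 3, crossing 2 cell types with control C57BL6/JAX mice, hyperlipidemic LDLR-/-ApoB100/100 mice and type 2 diabetic IGF-II/LDLR-/-ApoB100/100 mice, and each sample pooled 3 to 4 mice. Every group is therefore a set of pooled animals, and differences between single mice are not visible.

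The values analysed are 7 comparison tables made by the authors, each for 1 pair of groups, with a row per promoter region. Per the file headers, each row holds a chromosome, start, end, strand, p-value, q-value and methylation difference, which are the column names of the methylKit package. Bismark 0.10.0, Bowtie2 2.0.5, methylKit 0.9.2, R 3.0.1 and the mouse build mm10 are named in the submitters' processing notes, with no role or order. The deposited p-values and q-values lie between 0 and 1, and the deposited difference is in percentage points of methylation, with both signs. Read filters, the minimum coverage, the way the 3 samples of a group were combined and the source of the promoter annotation are not given in the sources used here.

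No column holds a value per sample, a read count or a coverage, so the sequencing depth behind each value is unknown and no standard deviation between replicates could be computed. A p-value from reads pooled over samples measures mainly counting error and is smaller than one that includes the spread between pools. Which kind the authors' deposited p-values are is not stated. The q-value is used as deposited, and some p-values and q-values are listed as 0. An approximate standard error (SE) of a difference was taken as its size divided by the normal quantile of its two-sided p-value, with p-values floored at 1e-16, so that it is an upper bound where p is listed as 0.

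The tables hold 5686 different regions, each 1501 bp long and each on the minus strand. No region of a plus-strand gene was analysed here. Regions carry no gene name in the files, so names were taken from RefSeq gene positions on GRCm38.p6, which has the coordinates of mm10. A region was named after the gene whose last base lies inside it and nearest to the point 500 bp from its start, the position of the transcription start of a minus-strand gene with 1000 bp upstream and 500 bp downstream. This named 4850 regions (85.3%) after 4631 genes, with an exact match of the start for 2270 and a distance of up to 100 bp for 3634. Windows moved by 5000 bp to either side contained a gene end in 4.70% of cases, and 0 regions matched the start of a gene in plus-strand geometry. Another 832 unnamed regions lay inside an annotated gene, as alternative starts would, and are described as lying inside that gene. Exon and intron positions were not used, because only gene boundaries were available. Windows of neighbouring starts overlap, and can then share reads. Names whose annotated start lies over 100 bp from that of the region are less secure.

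The header does not say which group was subtracted. For each disease model the 4 differences around the square of 2 cell types and 2 conditions were added with every choice of signs. They closed to within 1.28e-13 percentage points over 3458 regions when each table was read as one group minus the other in 1 common order, while the best other choice of signs left a median of 1.18 points. The remaining choice between the 2 common orders was set by genes of known lineage, and all differences below are the second group minus the first, disease minus control or endothelial minus macrophage. Among fixed marker genes past the thresholds, 1 of macrophages was higher and 2 of endothelial cells were lower in the endothelial cells of hyperlipidemic mice, too few for a firm choice (two-sided Fisher's exact test, p = 0.333). A further check was chosen after the data were seen. Among 2921 autosomal regions with relative levels for 6 groups, several groups shared exactly the lowest level in 245 regions and exactly the highest level in 2, within 1e-09 points (two-sided exact binomial test over regions, p = 2.7e-70). Groups without a methylated read share a level of 0%, and CpG-rich promoters are known to be mostly unmethylated, while the other order would put those 245 shared levels at the top of the range. The order of subtraction therefore rests on this check and that background knowledge. Every rise, fall, share and level bound reported would be mirrored under the other order. The closure also fixes bounds on the level of each group, since no level lies under 0% or over 100%.

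A promoter was counted as changed at a q-value below 0.01 and a difference of at least 25 percentage points, the defaults of methylKit. Higher against lower counts were compared by a two-sided exact binomial test over promoters, which are not independent replicates. For pairs of comparisons, the overlap was set beside n1 × n2 / N and the 2 differences of a region were compared as z from their SEs with Benjamini-Hochberg adjustment, at an adjusted p below 0.01 and at least 25 points. Where both comparisons used the same control libraries, 100 simulations of unchanged groups gave the values expected from that sharing. No values per sample were available for them, so they may lack the spread between pools, and their covariances may then be too low. The 27 gene lists, of which 26 had a measured member, were fixed before the data were examined, as were the thresholds and the tests of counts, overlaps, differences and lists. Each list was tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over all lists and comparisons, 176 tests of changed against unchanged members and 38 of direction. The difference test was checked on simulated values with the SEs of the tables. With both limits, on the adjusted p and on size, it recovered 96.9% of 98 regions shifted by 30 points and 0% of 102 shifted by 10 points among 3392 for hyperlipidemia, and 95.9% of 98 and 0% of 102 among 3350 for diabetes, and called 0% of unchanged regions in both. The limit on the adjusted p alone, which was not used for the counts, recovered 82.4% and 88.2% of the regions shifted by 10 points and called 0.0627% and 0.0952% of unchanged regions, for hyperlipidemia and diabetes. The simulated noise came from the same SEs that the test divides by. It therefore cannot show how many regions would be called through spread between pools that these SEs may lack. The 0% at 10 points follows from the 25-point limit.

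Genes were named by a fixed rule. In each comparison these are the 8 largest rises and the 8 largest falls among changed regions with 1 region per gene, leaving out predicted genes and small RNAs, then up to 4 changed members per list, the 8 genes changed in both models of a cell type with the largest mean, and the measured members of a list of genes remembered from the study's paper. Regions inside genes and the promoters changed in 3 cell type comparisons were chosen after their values were seen, and so were the tests on X-linked promoters, Fisher's exact tests of X-linked against autosomal rises with Benjamini-Hochberg adjustment over 7 comparisons, and 95% intervals of medians from 2000 bootstrap samples of regions. Alternatives changed the q-value, the minimum difference, the unit of counting and the chromosomes and genes included. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.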

Results

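Promoter methylation was measured in macrophages and endothelial cells sorted from ischemic calf muscle of control, hyperlipidemic and type 2 diabetic mice, with 3 pooled samples in each of 6 groups. Macrophages are the phagocytes that enter ischemic muscle, and endothelial cells line its vessels. Hyperlipidemic mice lack the LDL receptor and make only the ApoB100 form of apolipoprotein B, and diabetic mice carry an additional IGF-II transgene on that background. Controls were C57BL6/JAX mice, so mouse line and disease state cannot be told apart in any comparison of a disease model with control. The authors' 7 deposited tables covered between 3815 and 4762 minus-strand promoters each, of which 2959 were present in all 7. No values per sample were analysed, so every error below comes from the authors' p-values or q-values, which may not include the spread between pools, and the depth is unknown. Rises, falls and level bounds rest on an order of subtraction that the file header does not give and would be mirrored under the other order. Names are by position and less secure where the annotated start lies far from the region's, as for Mapkapk2 (328 bp), Polr2a (410 bp), Nobox (518 bp), Sp7 (764 bp) and Myh11 (780 bp). Rankings of genes leave out small RNAs, predicted genes and regions inside genes. Coordinates are mm10, and the changed promoters of each comparison are counted in the plot of calls.

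**Figure D1:**
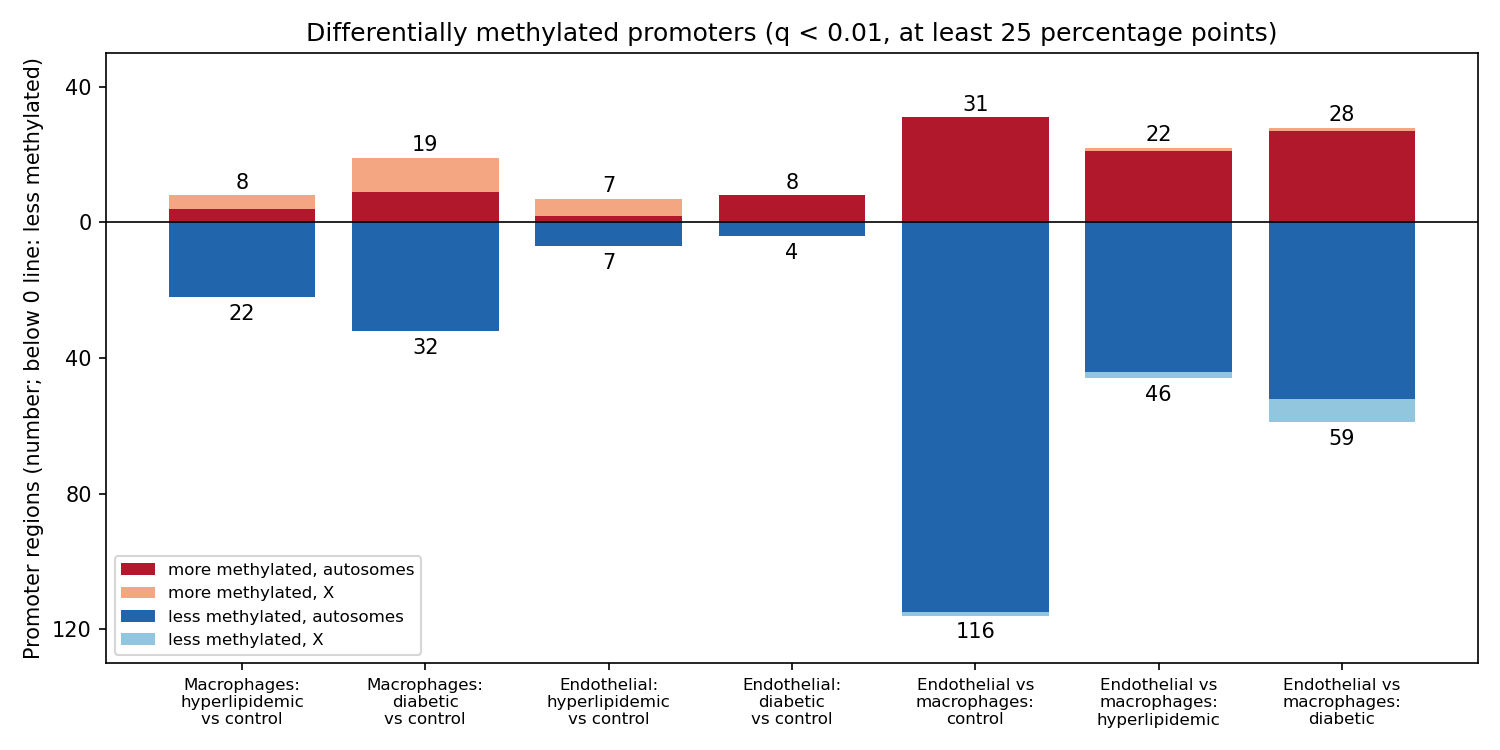
Number of promoter regions (y axis) that were more methylated (above 0) or less methylated (below 0) at q below 0.01 and a difference of at least 25 percentage points, for the 7 comparisons on the x axis, with X-linked regions in the lighter shade. Falls outnumbered rises most between control endothelial cells and control macrophages, 116 against 31, and 10 of the 19 rises in diabetic macrophages were X-linked.

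The first question was which promoters of muscle macrophages differ in hyperlipidemic mice. Sec13, a coat protein of vesicles leaving the endoplasmic reticulum (chromosome 6, 113740181 to 113741681), fell by 74.3 points in the authors' deposited table. Crtap, a partner of the collagen prolyl 3-hydroxylase (chromosome 9, 114390212 to 114391712), fell by 71.3 points there, and the coatomer subunit gene Arcn1 (chromosome 9, 44767308 to 44768808) fell by 42.4 points in the same authors' deposited table. With the order of subtraction used, the differences in the authors' deposited tables bound Sec13 at 74.3% or more in control and at 25.7% or less in hyperlipidemic macrophages. Other large falls in the authors' deposited table were those of Mfsd2b, a sphingosine-1-phosphate exporter of blood cells (-41.4), the potassium channel subunit Kcns1 (-39.4), the zinc finger gene Zfp14 (-37.9), the small GTPase gene Rab40b (-37.3) and Zfp750 (-34, q = 0.0051). Methylation rose most at Mapkapk2, which encodes a kinase downstream of p38 (chromosome 1, 131097043 to 131098543), by 52.7 points (SE 7.93, q = 3.5e-09) in the authors' deposited table. Igll1, a surrogate light chain gene of B cell precursors, rose by 44.3 points (SE 9.71, q = 0.00014) and Nkain1, whose product binds the sodium pump, by 29.9 points in the authors' deposited table. The remaining named rises in the authors' deposited table were X-linked: Nup62cl (28.7), Prrg1 (27.3) and the acetyltransferase gene Naa10 (25.5).

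In total 8 promoters rose and 22 fell among 3815, a share of rises of 26.7% (two-sided exact binomial test over promoters, p = 0.0161, adjusted p = 0.0282 over 7 comparisons). The share was 27.3% with 1 region per gene (exact binomial p = 0.0525) and 32% at a q-value below 0.001 (exact binomial p = 0.108), close to 26.7% but over fewer promoters. It was 15.4% without the X chromosome (exact binomial p = 0.00053) and 33.8% at 10 points (exact binomial p = 6.9e-05). Of the 8 rises, 4 were on the X chromosome, which held 50 of the tested regions (two-sided Fisher's exact test, adjusted p = 4.1e-06). The median difference of X-linked promoters was 8.74 points (95% bootstrap interval 5.69 to 11.5), against -0.133 on autosomes, in values from the authors' deposited table.

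The second comparison asked the same of macrophages from diabetic mice. Ddhd1, a phospholipase gene (chromosome 14, 45657643 to 45659143), had the largest fall, 74.8 points lower, written as a difference of -74.8 in the authors' deposited table. Arcn1 (-60.3), Sec13 (-56.2), the F-box gene Fbxw2 (-54.6) and Rab40b (-43.2) followed in the authors' deposited table, then the collagen VI gene Col6a1 (-39.8), Klhl40, which stabilises the thin filament of skeletal muscle (-38.4), and Kcns1 (-38.3). The phosphodiesterase gene Pde11a (chromosome 2, 76338153 to 76339653) rose by 57.8 points (SE at most 6.96) in the authors' deposited table, though its annotated start lies 492 bp from that of the region. Sh3glb2 (35.4) and Ccdc124 (34.3) were the other autosomal genes among the 8 largest rises named by the fixed rule in the authors' deposited table. X-linked genes made up the rest of them in the authors' deposited table, with Tro (35.0), Cmc4 (34.6), Wdr13 (32.4), the mRNA export gene Thoc2 (30.8) and the proteasome chaperone gene Psmd10 (29.9).

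In all, 19 promoters rose and 32 fell among 4431 in diabetic macrophages, a split that did not pass the test (37.3% rises, exact binomial p = 0.0919). Without the X chromosome the share of rises was 22.0% (exact binomial p = 0.00043), since 10 of the 19 rises were X-linked (Fisher's exact test, adjusted p = 3.9e-13). X-linked promoters had a median of 18.1 points (interval 12 to 19.7) in the authors' deposited table, against -0.198 on autosomes. Of 72 regions on the X chromosome, 64 were above 0, and 50 rose while 2 fell at a q-value below 0.01 with no limit on size.

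**Figure D2:**
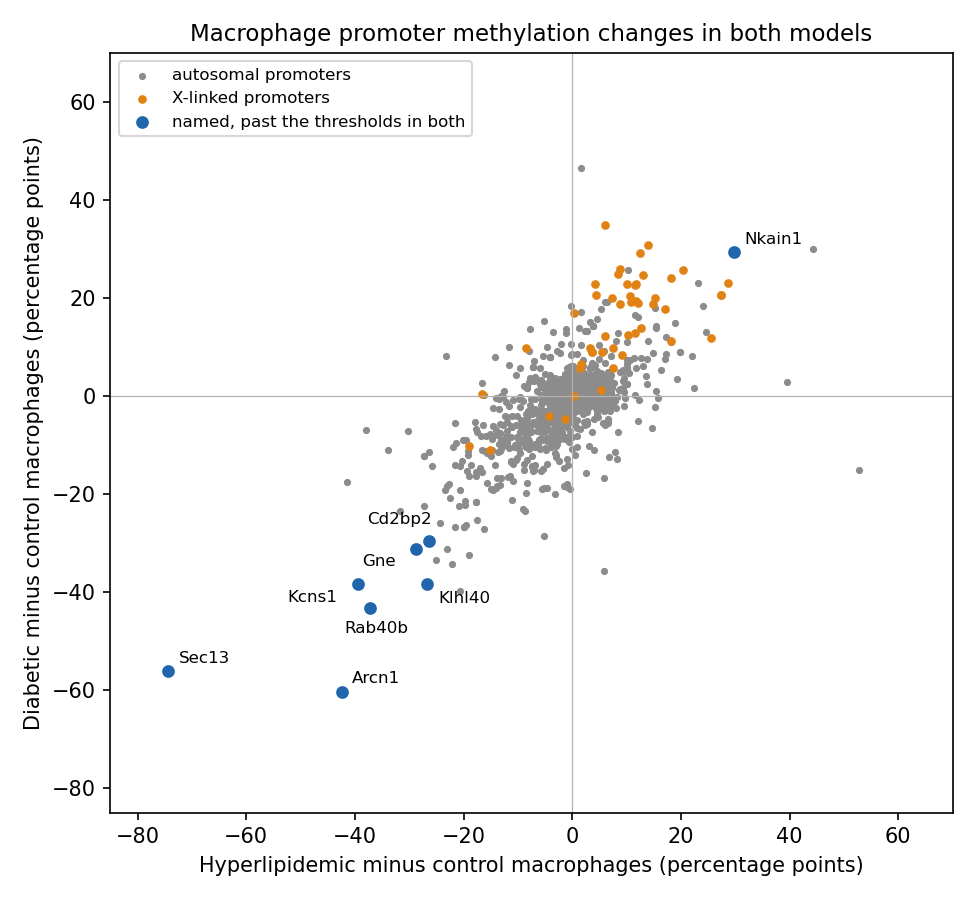
Methylation difference from control macrophages in percentage points for hyperlipidemic (x axis) and diabetic (y axis) macrophages, with 1 point per promoter measured in both. Grey points are autosomal, orange points X-linked, and blue points mark the 8 named genes past the thresholds in both models, of which Nkain1 is higher and Sec13, Arcn1, Rab40b, Kcns1, Klhl40, Gne and Cd2bp2 are lower.

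Both macrophage comparisons changed 9 promoters in common among 3545 measured in both, 1 up and 8 down, and all 9 had the same sign. Sec13, Arcn1, Rab40b, Kcns1, Klhl40, the sialic acid synthesis gene Gne (-28.7 and -31.3) and Cd2bp2 (-26.3 and -29.6) fell in the hyperlipidemic and diabetic columns of the authors' deposited tables. Nkain1 rose by 29.9 and 29.3 points in the authors' deposited tables, and the last common region lay inside C77080 (-25.1 and -33.4), a name given after its value was seen. Independent lists would share 0.0181 rises and 0.107 falls. The 2 sets of differences correlated across promoters with Pearson's r = 0.675 and Spearman's rho = 0.463, promoters not being independent replicates. The same control libraries entered both, and simulated unchanged groups gave r = 0.433 and a covariance of 1.5 against 18.4 observed, so part of the excess overlap may come from the shared controls, which could not be split. A test of the difference between the models, with the SEs treated as independent, found 6 promoters that differed by at least 25 points. Mapkapk2 was one of them, with 52.7 points in hyperlipidemic and -15.2 points in diabetic macrophages in the authors' deposited tables (adjusted p = 1.6e-10), and the others were Zfp14, Tro, Vmn2r29 and regions inside Smc5 and Bcar1.

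In endothelial cells of hyperlipidemic mice, 7 promoters rose and 7 fell among 4762, and no autosomal or X-linked promoter reached 40 points. The share of rises was 22.2% over 9 promoters without the X chromosome (exact binomial p = 0.18). It was 64.5% at 10 points with the X chromosome included (exact binomial p = 0.0035). At a q-value below 0.01 with no limit on size, 46 X-linked promoters rose and 1 fell, but 63 of 159 autosomal ones rose. Rcan1, an inhibitor of calcineurin, fell by 32.2 points (q = 2.4e-05) in the authors' deposited table, and the chondromodulin gene Cnmd fell by 30.2 points (q = 0.0037) there. Klkb1, which encodes plasma prekallikrein (chromosome 8, 45294335 to 45295835), fell by 28.0 points (SE 6.46, q = 0.00058) in the authors' deposited table. Other falls in the authors' deposited table were at Nkain4 (-28.9), Mrps21 (-28.5, annotated start 895 bp away) and the actin-binding drebrin gene Dbn1 (-27.8). Rises in the authors' deposited table were at the autosomal genes Plekhb1 (28.9) and Atg14, an autophagy gene (27.7), and at the X-linked genes Sat1, of polyamine breakdown (31.4), Gnl3l (30.9), Snx12 (25.5) and Slc25a53 (25.1). The X chromosome held 5 of the 7 rises (Fisher's exact test, adjusted p = 1.6e-07), and its median difference was 11.7 points (interval 7.63 to 13.6) in the authors' deposited table, against 0 on autosomes.

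In endothelial cells of diabetic mice, 8 promoters rose and 4 fell among 4033 (66.7% rises, exact binomial p = 0.388). Over every deposited region of this comparison the direction was the reverse, with 1582 differences above 0, 2370 below 0 and 81 at exactly 0, a share above 0 of 40.03% without the last (exact binomial p = 3.5e-36). These differences were small, with a median of -0.198 points and quartiles of -0.813 and 0.433. The tilt was not particular to this comparison, since the share was between 39.9% and 44.1% in the macrophage and cell type comparisons too. Nkain1 (30.9), Snx22 (29.5), Mfsd2b (26.7), the NF-kB inhibitor gene Tnip1 (26.4), Carns1 (25.6) and Polr2a, the large subunit of RNA polymerase II (25.6), rose in the authors' deposited table. Falls in the authors' deposited table were at Klkb1 (-32.4), Col26a1 (-32.3), Tjap1 (-26.2) and a region inside Ptges and Gm52550 (-28.4). None of the 8 rises was X-linked, and the X median was 2.90 points (interval -0.298 to 5.13). The 2 endothelial comparisons shared 2 promoters of 3842, Klkb1 and the region inside Ptges, both lower, where independent lists would share 0.00625 falls. Across promoters r was 0.527, against 0.438 from simulated unchanged groups with shared controls, and the covariance was 6.87 against 1.17. The simulated covariances, here and in macrophages, may be too low if the deposited p-values lack the spread between pools. Nkain1 and the kinase subunit gene Csnk2a2 differed between the models, Csnk2a2 with -22.8 points in hyperlipidemic and 22.0 points in diabetic endothelial cells in the authors' deposited tables (adjusted p of the difference 2.9e-28).

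**Figure D3:**
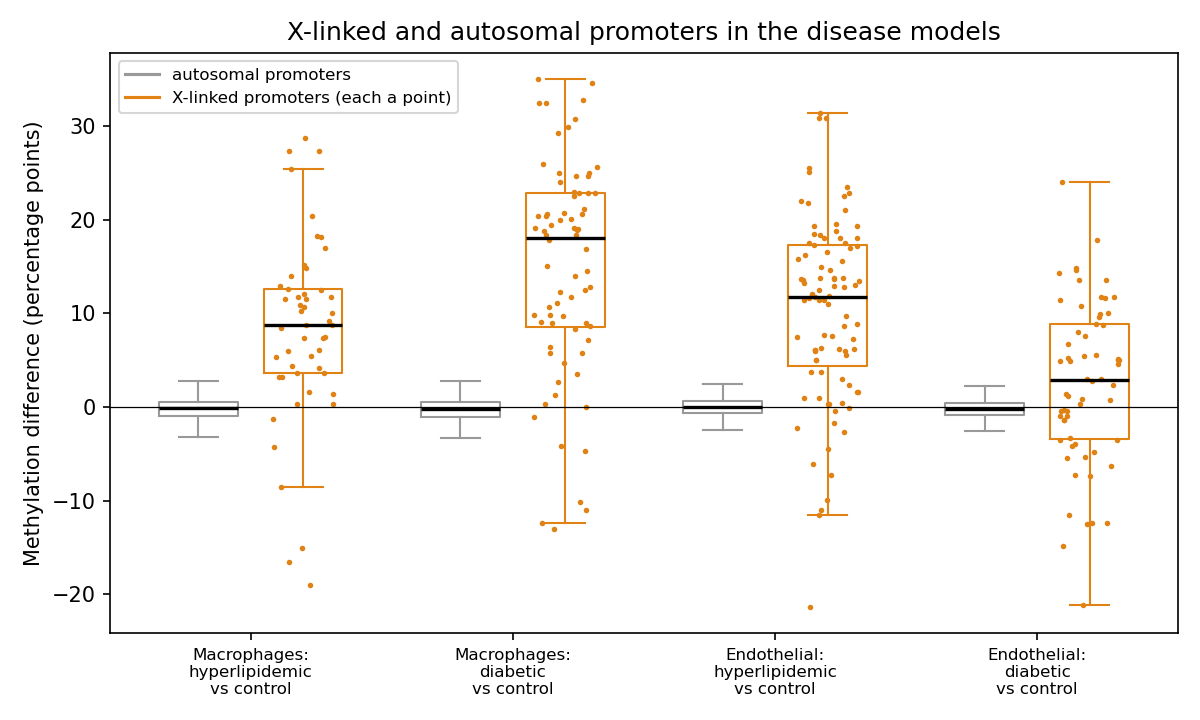
Methylation difference from control in percentage points (y axis) for autosomal (grey) and X-linked (orange, each promoter a point) promoters in the 4 comparisons of a disease model with control (x axis). Boxes span the quartiles with the median as a line, and whiskers reach to 1.5 times the box length without outlying autosomal points. The X-linked median was 18.1 points in diabetic macrophages, 11.7 in hyperlipidemic endothelial cells, 8.74 in hyperlipidemic macrophages and 2.90 in diabetic endothelial cells.

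Changes in macrophages and endothelial cells of the same model were then compared. For hyperlipidemia the 2 cell types shared 0 changed promoters of 3458, with 23 and 5 changed among them, and 49.9% of all promoters had the same sign. Independent lists would share 0.00521 rises and 0.00983 falls, so with so few calls the 0 says little about how far the cell types differ. At 10 points 24 were shared, and r across promoters was 0.177. For diabetes the 2 cell types shared 2, with 38 and 10 changed, of which Nkain1 rose in both and Snx22 went opposite ways, -33.9 in macrophages and 29.5 in endothelial cells in the authors' deposited tables. Tests of the difference itself found 31 promoters for hyperlipidemia and 38 for diabetes. Ddhd1 differed most for diabetes, with -74.8 points in macrophages and 18.3 in endothelial cells in the authors' deposited tables. Zfp750 differed most for hyperlipidemia, with -34 and 25.2 points in the authors' deposited tables, though its endothelial rise alone did not pass the q-value limit.

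The largest differences lay between the cell types. In control mice 31 promoters were more and 116 less methylated in endothelial cells than in macrophages (21.1% higher, exact binomial p = 9.4e-13). Higher in endothelial cells were Hk3, a hexokinase of myeloid cells (chromosome 13, 55020319 to 55021819, annotated start 656 bp away), by 68.3 points, and Dock2, a Rac activator of leukocytes (chromosome 11, 34783405 to 34784905), by 55.6 points in the authors' deposited table. Abca9 (56), Gpr20 (44.1), Ifitm6 (40.7), Nkain4 (36), Hes3 (35.4) and Csnk2a2 (34.8) completed the 8 largest named by the fixed rule in the authors' deposited table. Lower in endothelial cells were Ang2, a ribonuclease of the angiogenin family (chromosome 14, 51195423 to 51196923), at -88.0 points, and the arginine methyltransferase gene Prmt6 (chromosome 3, 110250499 to 110251999), at -86.2 points in the authors' deposited table. These values place Ang2 at 88.0% or more in control macrophages and at 12% or less in control endothelial cells, from the authors' deposited table. Crtap (-81.4), the lipid kinase gene Pip4k2c (-78.7), Ddhd1 (-71.9), the endothelial exchange factor gene Arhgef15 (-62.3), Cbr2 (-56.4) and Gne (-54.3) followed in the authors' deposited table.

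Hyperlipidemic mice had 22 promoters higher and 46 lower in endothelial cells (exact binomial p = 0.0049), and diabetic mice 28 and 59 (p = 0.00117, exact binomial). The channel gene Calhm6 (64.3), Grip1os2 (30.3), Mpp4 (-47.3), Acss2os (-47.9) and the cortistatin gene Cort (-46.7) stood among the 8 largest rises or falls of hyperlipidemic mice named by the fixed rule in the authors' deposited table. Lnx1 (-70.0), the X-linked Magix (-64.9), Hhla1 (-39.6) and Tlr12, a Toll-like receptor gene (37.2), stood among those of diabetic mice in the authors' deposited table. In 2959 promoters covered in the 3 conditions, 25 passed the thresholds in each, 8 higher and 17 lower in endothelial cells and none in opposite directions. These 25 regions carried 6 gene names on the higher side, Hk3, Dock2, Abca9, Gpr20, Ifitm6 and the long non-coding RNA gene Mirt2. On the lower side they carried 12, among them Prmt6, Cbr2, Parp12, Timd2, the osterix gene Sp7, the myoblast fusion gene Mymx, Hoxa6 and Clec14a, names chosen after the values were seen.

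**Figure D4:**
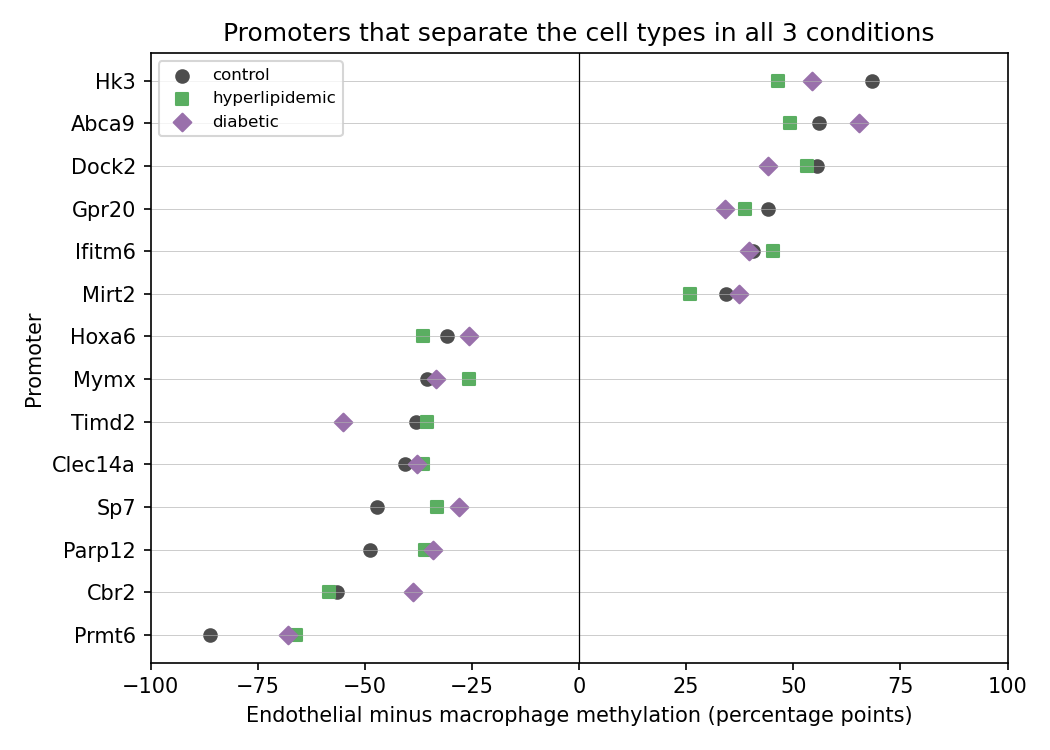
Endothelial minus macrophage methylation in percentage points (x axis) for 14 named promoters, 1 region per gene (y axis), past the thresholds in control (circles), hyperlipidemic (squares) and diabetic (diamonds) mice. Hk3, Abca9, Dock2, Gpr20, Ifitm6 and Mirt2 lie above 0 in the 3 conditions and the other 8 below 0, with Prmt6 at -86.2, -66.0 and -68.0.

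Few members of the marker lists passed the thresholds, and the directions of the macrophage and endothelial markers are no separate result, since the order of subtraction was first chosen with them. Dock2 was the changed member of the macrophage lineage list in each condition, with 55.6, 53.3 and 44.0 points in control, hyperlipidemic and diabetic mice in the authors' deposited tables, among 2 measured members in control and 3 in hyperlipidemic mice. Of the endothelial list, with 5 members measured in control and 4 in hyperlipidemic mice, Clec14a, a lectin of endothelial cells, was lower in endothelial cells at -40.5, -36.3 and -37.9 points, and the receptor gene Tie1, also of the angiogenesis list, at -43.1 points in hyperlipidemic mice, in the authors' deposited tables. Changed against unchanged members of this list gave an adjusted p of 0.0953 in hyperlipidemic mice by Fisher's exact test. Of proinflammatory and chemokine genes, Cxcl10, an interferon-induced chemokine, was lower in endothelial cells by values of -45.3 in control and -42.8 in hyperlipidemic mice in the authors' deposited tables. Of 14 lipid genes with a region in any table, the Wnt co-receptor gene Lrp5, also the changed member of the Wnt list, (-39.8, control) and the HDL receptor gene Scarb1 (-27.5 and -27.0, hyperlipidemic and diabetic) were lower in endothelial cells in the authors' deposited tables. The mural cell gene Myh11 was lower in control and diabetic endothelial cells (-28.2 and -26.5), and the myeloid factor gene Cebpe higher (27.9 and 27.2), in the authors' deposited tables. Lymphocyte gene Rag1 was higher by 29.0 points in hyperlipidemic endothelial cells in the authors' deposited table, and the germline gene Nobox (-33.0) and the keratin gene Krt39 (-25.2) were lower in control endothelial cells in the authors' deposited table.

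None of the 38 tests of direction and 2 of the 176 tests of changed members passed an adjusted p of 0.05, both for microRNA genes between the cell types. In control mice 4 were higher and 5 lower of 72 measured, a changed share of 12.5% against 2.80% of other genes (Fisher's exact test, adjusted p = 0.0405). In hyperlipidemic mice 2 were higher and 4 lower of 61 (9.84% against 1.52%, Fisher's exact test, adjusted p = 0.0405). Mir142b, at a locus of blood cells, was higher in endothelial cells by 57.2 and 48.5 points and Mir3058 was lower at -72.9 and -66.9 points in the authors' deposited tables. Mirt2 is not a microRNA but matched the name pattern, and without it the changed share was 11.3% of 71 and 8.33% of 60, with adjusted p = 0.0915 and 0.121 by Fisher's exact test, so that smaller counts of a similar share did not pass. Members of 6 lists changed in a disease comparison. These were microRNA (Mir5131, whose window overlaps most of that of Ddhd1 and is not independent of it, at -42.0, Mir6537 at -25.7 and Mir3082 at -25.3 in diabetic macrophages, Mir1936 at 32.4 in diabetic endothelial cells), collagens (Col6a1, Col26a1), mural genes (Col6a1), complement (Serping1, also a gene of the study's paper) and chemosensory receptors (Vmn2r29 at -35.7), with values from the authors' deposited tables.

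Lists for alternatively activated macrophages, developmental transcription factors, epigenetic enzymes, imprinted genes, insulin and glucose genes, interferon genes, semaphorins with their receptors and skeletal muscle had no changed member in any comparison. The semaphorin list held 1 measurement of 1 gene. Regions inside genes did not count for lists, such as one inside Igf2 at -47.2 points (q = 7.1e-06) between the cell types of hyperlipidemic mice in the authors' deposited table. Outside these lists, the interferon-induced Cxcl10 and the muscle genes Klhl40 and Mymx did change, so the classes as a whole were not unchanged. Over these 8 lists, 119 of 466 measurements had an unadjusted p below 0.05 in the authors' deposited tables. Counts adjusted over the list alone were the same as those over all promoters in each of the 176 list counts.

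Of the genes remembered from the study's paper, 7 were covered, and as a list chosen on these samples they are not independent evidence. Serping1, the C1 inhibitor of complement (chromosome 2, 84774929 to 84776429), was lower in both macrophage comparisons of the authors' deposited tables, at -24.4 points (SE 3.07, q = 4.9e-13) in hyperlipidemic and -25.8 points (SE at most 3.11) in diabetic mice. The first of these lay just short of the 25-point limit. Endothelial differences of Serping1 were -2.29 (q = 0.33) and -3.65 (q = 0.14) in the authors' deposited tables, and the control endothelial minus macrophage difference was -47.1. Tnfsf15, a TNF family cytokine (chromosome 4, 63744613 to 63746113), had -19.7 (q = 0.0023) and -21.3 points (q = 0.00022) in macrophages and -38.7 between the control cell types in the authors' deposited tables. Cdk18 had 13.0 points (q = 4.3e-08) and 6.15 points (q = 0.011), and the tyrosine kinase gene Fes 9.49 points (q = 5.6e-05) and 0.837 points (q = 0.58), in hyperlipidemic and diabetic macrophages of the authors' deposited tables. The complement factor B gene Cfb had -11.7 points (q = 0.021) and 6.30 points (q = 0.10) in those macrophages, and arginase gene Arg1 6.36 points (q = 0.0036) in diabetic ones, in the authors' deposited tables. Cxcr4 was covered between the control cell types, with 0.630 points (q = 0.55) in the authors' deposited table.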

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

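The tests in this part were fixed before the data were examined. Promoters whose change in macrophages differed from that in endothelial cells of the same disease model, by a test of the difference itself, numbered 31 for hyperlipidemia and 38 for diabetes. These tests rest on p-values of the authors' deposited tables, which do not state whether the spread between pools is included. Other splits of the samples could not be counted without values per sample, so chance between pools is not excluded.

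For hyperlipidemia, the macrophage change minus the endothelial change was -59.2 points at Zfp750, -56.7 at Sec13, -43.1 at Mfsd2b, -40.6 at Kcns1, -36.6 at Plekhb1 and -26.3 at Rab40b. It was 43.9 points at Nkain1 and 37.2 at Mapkapk2.

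For diabetes, that difference was -93.1 points at Ddhd1, -63.4 at Snx22, -51.9 at Fbxw2, -44.2 at Mfsd2b, -42.4 at Kcns1, -37.8 at Col6a1 and -37.3 at Rab40b. It was 36.3 points at Tro and 27.6 at Wdr13, both X-linked. Regions that differed in both models, which share their control libraries, were Mfsd2b, Kcns1, Rab40b, Cd2bp2 (-25.9 and -25.8 points for hyperlipidemia and diabetes) and a region inside Nyap1 (-44.8 and -47.9), the last one named after its values were seen.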

How the results depend on the processing

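The microRNA alternatives were chosen after seeing the data, and the other alternatives before the data were examined. No paired analysis was possible because the deposited tables hold no values per sample, and for the same reason leaving out a replicate, a replicate block, a coverage minimum and other splits of the samples were not run. A q-value limit of 0.05 and leaving out predicted and small RNA genes kept each count within 1.5 times and each share on its side of the test. In the order hyperlipidemic and diabetic macrophages, hyperlipidemic and diabetic endothelial cells, then control, hyperlipidemic and diabetic cell type comparisons, the counts were 154, 214, 107, 80, 330, 239 and 283 at 10 points, 7, 8, 0, 0, 41, 25 and 15 at 40 points, and 3815, 4431, 4762, 4033, 4524, 3894 and 3931 for every deposited region. The share of rises in hyperlipidemic macrophages missed the test at a q-value limit of 0.001 (32%), at 40 points (28.6%) and with 1 region per gene (27.3%), where fewer regions were counted. In diabetic macrophages it passed at 10 points (36.9%), for every deposited region with a difference other than 0 (42.0%) and without the X chromosome (22.0%). In hyperlipidemic endothelial cells it passed at 10 points (64.5%), while without the X chromosome 9 promoters were counted and the share, 50% with it, was 22.2%. The 64.5% includes the X chromosome, and of autosomal promoters at a q-value below 0.01 of any size, 63 of 159 rose. In diabetic endothelial cells every deposited region with a difference other than 0 gave 40.03%, the reverse of the called promoters, and the cause was not tested. Between cell types of diabetic mice it missed at 40 points (33.3%).

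Overlaps in every region of both tables covered 3545 promoters with 63.7% of the same sign for the models in macrophages, 3842 with 64.2% for the models in endothelial cells, 3458 for either cell type pair of a model and 2959 with 34.6% of 1 sign in all 3 cell type comparisons. A share over 3 comparisons is lower by its nature than one over 2. Taken in pairs, the cell type comparisons had 55.4%, 55.3% and 55.6% of the same sign. For the models, simulated unchanged groups with shared controls gave 63.5% for macrophages and 63.7% for endothelial cells. The shares over every region, large and small differences alike, thus show no agreement of the models beyond the shared controls. They do not speak to the larger differences alone. At 10 points the overlaps were 74 (98.6% of the same sign), 30 (93.3%), 24 (hyperlipidemia), 25 (diabetes, 80%) and 91 (96.7%). No simulated share is given at that limit, so the part of the shared controls in the first 2 is unknown. At 40 points the overlaps were 2, 0, 0, 0 and 4, with no share where none was shared. Matched by gene symbol, the endothelial overlap was 1. At 10 points 6 list tests passed. By Fisher's exact test, without Mirt2 the microRNA list had 8 (adjusted p = 0.0915) and 5 (adjusted p = 0.121) changed genes in control and hyperlipidemic mice, while without overlapping windows it had 8 (adjusted p = 0.0281) and 6 (adjusted p = 0.0132). The list without overlapping windows still included Mirt2, and the other genes were not filtered for overlap (2.80% and 1.52% changed). It therefore does not show that the result holds for microRNA genes alone. Sequencing depth is unknown, so the smallest detectable difference was not derived from it.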

Other observations

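The tests of both patterns weighed in this part were chosen after the results they bear on had been seen, and so were the regions lying inside genes. No theme was tested among them, and these are examples. In the authors' deposited tables the region inside the phosphatase gene Ptpn6 was higher in endothelial cells by 54.2 points in control and 39.5 in diabetic mice. The region inside the adaptor gene Dok3 was higher by 42.2, 33.9 and 26.3 points, and that inside the kinase gene Rps6ka1 by 53.6, 27.6 and 34.1 points, in control, hyperlipidemic and diabetic mice of the authors' deposited tables. Inside the complement receptor gene C5ar2 the authors' deposited tables gave 46 points in control and 34.2 in hyperlipidemic mice. Inside the immune receptor adaptor gene Nfam1 the direction was the opposite, with -40.8 points in control and -45.7 in diabetic mice in the authors' deposited tables. Of the Hox list, Hoxa9 was higher in endothelial cells (33.7 in control, 30.4 in diabetic mice) and Hoxa6 lower (-30.9, -36.4 and -25.7 in control, hyperlipidemic and diabetic mice) in the authors' deposited tables.

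Macrophage promoters that were less methylated in endothelial cells lay nearer to the endothelial level in both disease models than in control macrophages, while at those more methylated there the intervals included 0 once no library was shared, over fewer promoters. With the cell type difference from control mice, whose macrophages enter both axes, the slope of the autosomal macrophage change on it was 0.343 for hyperlipidemia and 0.338 for diabetes, and with that of the other disease model, which shares no library, 0.170 (95% interval 0.0909 to 0.246, 60 promoters) and 0.124 (0.0341 to 0.205, 57 promoters). The latter slopes were 0.200 (0.113 to 0.289) and 0.174 (0.0702 to 0.259) at promoters lower in endothelial cells, which argues against the shared control libraries as the whole cause there, and 0.114 (-0.0476 to 0.252) and -0.013 (-0.254 to 0.159) at those higher, where the shared libraries cannot be told apart from a change. The endothelial change gave slopes of 0.0871 (0.0333 to 0.147) and 0.0375 (-0.0757 to 0.155) at those lower, for hyperlipidemia and diabetes with no library shared. At those higher the endothelial slopes were -0.128 (-0.243 to -0.0277) and -0.0165 (-0.143 to 0.11). A smaller change in the same direction at promoters lower in endothelial cells was thus also present in hyperlipidemic endothelial cells. Non-blood cells that passed the flow cytometry sort are a candidate explanation and would move both kinds of promoter towards the endothelial level, and the median share gained was 0.254 (0.0502 to 0.353, 40 promoters) and 0.201 (0.0411 to 0.316, 39 promoters) at those lower in endothelial cells, as this would give, though these promoters are those that show the pattern, and 0.217 (-0.0065 to 0.349, 20 promoters) and 0.087 (-0.192 to 0.269, 18 promoters) at those higher. The fixed endothelial marker Clec14a had -8.95 points (q = 0.14) and -7.30 points (q = 0.19) in the authors' deposited macrophage tables, the direction such cells would give. At the fixed macrophage marker Dock2 the lower level bound, which moves with the level, was 0% in control, 15.4% in hyperlipidemic and 14.4% in diabetic macrophages. That is also towards the endothelial level, but the q-values of Dock2 in the macrophage comparisons are not given here, so no weight is put on it. The last 2 intervals of the share include 0, and the 2 kinds of promoter would trade places under the other order of subtraction. Such cells therefore cannot be told apart from a change within macrophages, and the disease state or mouse line stays open as untested.

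X-linked promoters were more methylated than in controls in both macrophage comparisons and in hyperlipidemic endothelial cells, with a lower median in diabetic endothelial cells, at 2.90 points (95% interval -0.298 to 5.13), or 3.02 (0.778 to 5.27) without escape genes, and 17 rose and 4 fell at a q-value below 0.01. The autosomal median of -0.198 points in diabetic macrophages argues against a gain over all chromosomes. With the order of subtraction used, more female mice in the disease pools (in the control pools under the other order) are a candidate explanation, since promoters of the inactive X are methylated and the labels give no sex, and the 3 covered genes that escape inactivation had medians of 1.40 points in hyperlipidemic macrophages and 0.325 in hyperlipidemic endothelial cells, against 9.20 (5.95 to 11.7) and 11.9 (8.85 to 13.6) at other X-linked promoters, as this would give, and 5.73 against 18.3 (12.3 to 20) in diabetic macrophages, with 25 at 1810030O07Rik, but 3 genes are too few to decide. The same mixture of mice in both cell types would leave the X difference between them as in controls, 1.47 points (-0.651 to 3.31), which the median of 1.92 (-0.401 to 6.61) in hyperlipidemic mice was consistent with, whereas -10.6 (-13.4 to -8.37) in diabetic mice argues against it there. In hyperlipidemic mice more females and the disease state both stay open, and in diabetic mice different mice in the pools of each cell type and the disease state stay open as untested. Mouse line differs between the control and disease groups and cannot be told apart from the disease state in either model.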
